A study of Homo sapiens with 8 samples.

How the data were processed

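The series holds 8 samples of CCRF-CEM cells: 6 nascent strand libraries, 1 for each of parental and SLFN11-KO cells treated with DMSO, camptothecin, or camptothecin and VE-821, and 2 samples of sheared genomic DNA, 1 per line, whose own files were not used here. Groups were taken from the sample titles. Each nascent strand library came with a MACS2 list and a SICER list, 12 lists in all.

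Per the labels' protocols, DNA from cultures that were not synchronised was size-fractionated and digested with exonuclease, and Illumina paired-end libraries were sequenced. Per the submitters' processing notes, MACS2 and SICER were used and coordinates are on hg19. Per the file headers of 5 MACS2 lists, the authors called broad peaks for each library separately with MACS 2.1.0.20140616 at a q-value of 0.01, without a fragment model, extending tags to 200 bp, keeping at most 2 duplicates per position, and scaling the larger library down to the smaller. Library names in these headers point to bwa mem, whose version is not given in the sources used here. Per the file headers, the control of each list was the sheared genomic DNA of the same line, with 46247099 filtered tags in parental and 46447484 in SLFN11-KO cells. The names of the SLFN11-KO lists point to the parental genomic DNA instead; the headers were followed, and every comparison between the lines rests on this. The list of SLFN11-KO cells with camptothecin and VE-821 has no header, so its depth, control and settings are not given in the sources used here. Tag length per the file headers was 70 bp in both camptothecin libraries, and 66 bp, 65 bp and 63 bp in parental DMSO, SLFN11-KO DMSO and parental camptothecin with VE-821.

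The pileup column deposited by the authors is a coverage signal per peak, scaled to the control library. The other 3 columns are headed −log10 p, fold enrichment and −log10 q per the file headers, but in all lists the values under q exceeded those under p in 100% of peaks, and fold exceeded pileup plus 1 in 100%. They were therefore treated as scores of the authors' caller and used only to rank or filter peaks. Scores of separately called lists may not be comparable. Peak numbers above a common minimum score can thus differ between lists for that reason alone. The deposited SICER lists give a read count per island, not normalised, and a signal in reads per bp of island. Their settings are not given in the sources used here, and islands began at multiples of 200 bp and lay at least 800 bp apart. A final line of means in 4 SICER lists was left out. Calling each library separately means that depth and background can change which weak peaks appear in a list.

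Peaks on chromosomes 1 to 22 and X were kept. The numbers and widths of peaks, the log2 ratio of peak numbers and the overlap of lists were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A peak was shared if it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 100 circular shifts of each chromosome, and, chosen after seeing the data, from 100 shifts by 20 to 100 kb. Intervals for shares are 95% Wilson intervals, and those for ratios are exact conditional binomial intervals. They count peaks as independent and cover counting error only. The comparisons were 7 pairs of libraries fixed before the data were examined: camptothecin over DMSO and camptothecin with VE-821 over camptothecin in each line, and SLFN11-KO over parental cells in each treatment. With 1 library per group no comparison of a pair of libraries was tested. Chosen after seeing the data, lines were paired over the 3 treatments in an exact sign-flip permutation test, two-sided, whose smallest p is 0.25.

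For the baseline density analysis, 2887 bins of 1 Mb with a peak were ranked by the DMSO list of the line that was not being compared, or of parental cells for comparisons between lines under camptothecin. MACS2 bins were ranked on MACS2 peaks and SICER bins on islands. Errors are from a jackknife over 23 chromosomes. Regions for read shares, chosen after seeing the data, were unions of SICER islands of which every list called at least 50% of the length: 31176 of 193159 regions, holding 63.1% to 69.0% of the island reads of a library and 281.9 to 287 Mb of islands per list. Reads were taken as shares of the reads in these regions, which removes a common factor of depth. The regions were chosen from the compared lists themselves, so weak regions that a camptothecin list missed were left out. That choice can shrink or turn the read differences between quintiles. A shallow list can still miss parts of a weak region, so the covered length, the reads per covered bp and regions called over at least 80% of their length were examined too. Regions compared over 3 lists were unions of peaks of 1 line.

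The rule for naming genes needed an annotation of hg19. The gene table supplied with the data is of GRCh38, so no coordinates were taken from it: peaks were not assigned to genes, 11 gene lists fixed beforehand were not tested, and the position of gained and lost peaks relative to genes was not computed. The rule's fallback was used: among 1 Mb bins with at least 20 peaks summed over both libraries, the 5 with the highest and the 5 with the lowest log2 ratio, with a pseudocount of 0.5 and minus the genome-wide log2 ratio. Of these the text gives those whose 95% counting interval lay on 1 side of the genome-wide ratio, a choice made after seeing the data. The knockout of SLFN11 cannot be checked from these lists.

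Other settings fixed before the data were examined were SICER islands, a score of at least 10, merging of peaks within 1 kb, overlap of at least 50% of both peaks, lists cut to an equal length of 108611 peaks, and bins of 5 Mb. The lowest score in the MACS2 lists was 15.5, so the minimum of 10 removed no peak, and a minimum of 30 was added after seeing the data. The overlap, density and shift functions were tested on simulated lists and against bedtools 2.31.1, on the 220801 peaks of the parental DMSO list, and the largest of 7 deviations was 0.88%.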

Results

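Nascent strand sequencing was used to map where DNA replication started in CCRF-CEM cells, an established T-lymphoblastic leukaemia line. The method isolates short DNA strands newly made at replication origins and removes other DNA with lambda exonuclease, which spares strands that carry an RNA primer. Parental cells were compared with cells in which SLFN11 had been knocked out (SLFN11-KO). SLFN11 is a putative DNA and RNA helicase known to act on replication in cells under replication stress. Each line was treated for 4 h with DMSO, with 100 nM camptothecin, a topoisomerase I inhibitor that stalls replication forks, or with 100 nM camptothecin and 2 µM VE-821, an inhibitor of the checkpoint kinase ATR. The title of the series places the question in whether SLFN11 acts on stressed forks independently of ATR. There were 6 nascent strand libraries, 1 per line and treatment, and 2 samples of sheared genomic DNA. No group had a replicate, so no difference between groups could be set against a spread between replicates. Lines paired over the 3 treatments cannot give an exact sign-flip permutation p below 0.25, nor treatments paired over the 2 lines one below 0.5, so this test could not reach 0.05 here. Intervals below cover counting error only.

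The headers of the MACS2 peak lists gave 103346614 tags for parental cells with DMSO, 73769360 with camptothecin and 83608275 with camptothecin and VE-821. SLFN11-KO cells had 90069771 tags with DMSO and 64848139 with camptothecin. The depth of the SLFN11-KO library with camptothecin and VE-821 is unknown. Both camptothecin libraries were thus the shallowest of those with a known depth. In the SICER lists, islands held 52.6% of the tags in parental cells with DMSO and 54.9% in SLFN11-KO cells with DMSO. With camptothecin the islands held 46.7% of the tags in parental and 46.5% in SLFN11-KO cells, and with VE-821 added 53.1% in parental cells. Whether the SICER reads were counted after removal of duplicates is not given in the sources used here; as shares of the tags left after duplicate filtering in the MACS2 headers, the values ran from 47.9% in SLFN11-KO cells with camptothecin to 57.2% in SLFN11-KO cells with DMSO.

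On chromosomes 1 to 22 and X of hg19, parental cells had 220801 MACS2 peaks with DMSO, 233486 with camptothecin and 243367 with camptothecin and VE-821. SLFN11-KO cells had 229248, 217222 and 236208 peaks in the same order. The peaks covered between 250.1 Mb (parental cells, DMSO) and 287 Mb (SLFN11-KO cells, camptothecin and VE-821). Median peak width lay between 595 and 661 bp, and it was highest in the camptothecin library of each line, at 644 bp in parental and 661 bp in SLFN11-KO cells. SICER gave fewer and wider regions, from 178995 islands in parental cells with DMSO to 143508 in SLFN11-KO cells with camptothecin.

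**Figure D1:**
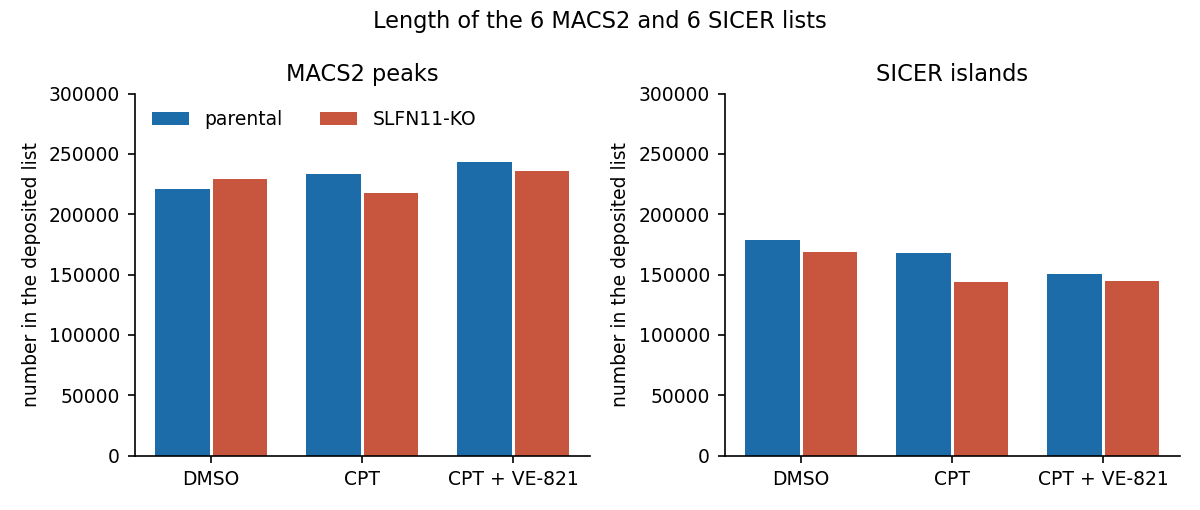
Number of MACS2 peaks (left) and SICER islands (right) for each treatment, with 1 library per bar, blue for parental and red for SLFN11-KO cells. Parental MACS2 peaks went from 220801 with DMSO to 233486 with camptothecin and SLFN11-KO peaks from 229248 to 217222, whereas SICER islands were fewer with camptothecin in both lines.

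The first question was what camptothecin did to the initiation map of parental cells, which carry SLFN11. The parental camptothecin library had 5.74% more MACS2 peaks than the DMSO library, a log2 ratio of 0.08 (95% binomial interval 0.07 to 0.09). Among 1 Mb regions, chromosome 10 from 32 to 33 Mb had 80 peaks with camptothecin and 42 with DMSO, chromosome 4 from 39 to 40 Mb had 69 and 38, and chromosome 6 from 154 to 155 Mb had 62 and 35. Chromosome X from 58 to 59 Mb, beside the centromere, had 45 and 24. In the opposite direction, chromosome 1 from 73 to 74 Mb had 10 peaks with camptothecin and 22 with DMSO. Relative to the genome-wide ratio, the log2 ratio with SICER islands was 0.50 against 0.77 with MACS2 peaks for the chromosome 4 region and 0.23 against 0.74 for that of chromosome 6. In SLFN11-KO cells the chromosome 10 region had 46 peaks with camptothecin and 60 with DMSO. That of chromosome 4 had 48 and 47, and that of chromosome 6 had 50 and 53. The regions of X (32 and 22) and chromosome 1 (13 and 18) moved as in parental cells. Regions named here and below were picked as extremes of their ratio, so part of each difference can follow from that choice. Of the parental camptothecin peaks, 71.9% (71.7% to 72.1%) overlapped a DMSO peak, against 17.5% after random circular shifts and 29.5% after shifts by 20 to 100 kb. The unshared camptothecin peaks were narrow, with a median of 341 bp against 836 bp for the shared ones. The direction of the genome-wide change depended on the peak list: the number of SICER islands changed by -6.22% with camptothecin (log2 ratio -0.09), and among MACS2 peaks with a score of at least 30 the log2 ratio was -0.38.

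In SLFN11-KO cells the camptothecin library had fewer peaks than the DMSO library, a change of -5.25% and a log2 ratio of -0.08 (-0.09 to -0.07). Among 1 Mb regions, chromosome 13 from 85 to 86 Mb had 8 peaks with camptothecin and 23 with DMSO, chromosome X from 97 to 98 Mb had 7 and 20, X from 83 to 84 Mb had 8 and 21, chromosome 4 from 19 to 20 Mb had 9 and 24, and chromosome 18 from 41 to 42 Mb had 9 and 23. Chromosome 11 from 50 to 51 Mb, next to the centromere, had 33 with camptothecin and 18 with DMSO, and chromosome 2 from 179 to 180 Mb had 49 and 28. In parental cells most of these regions moved the same way. The numbers there were 9 and 16 for X from 97 to 98 Mb, 8 and 13 for X from 83 to 84 Mb. They were 12 and 19 for chromosome 18, 13 and 15 for chromosome 13, 33 and 22 for chromosome 11 and 39 and 33 for chromosome 2. Chromosome 4 did not fall there, with 14 and 13. With SICER islands the rise on chromosome 2 in SLFN11-KO cells nearly vanished (25 with camptothecin and 28 with DMSO). Its relative log2 ratio was 0.07 against 0.87 with MACS2 peaks. The ratio in SLFN11-KO cells was 0.49 against 0.93 for chromosome 11 and -0.71 against -1.39 for chromosome 13. Of the camptothecin peaks, 76.4% (76.2% to 76.6%) overlapped a DMSO peak, against 18.9% after circular shifts and 31.8% after shifts by 20 to 100 kb. SICER islands were also fewer with camptothecin in SLFN11-KO cells (log2 ratio -0.23). The log2 ratio of SLFN11-KO cells was lower than that of parental cells by -0.16 in the MACS2 lists and by -0.14 in the SICER lists, a difference that was not tested. Among MACS2 peaks with a score of at least 30 it turned, to 0.05, with ratios of -0.38 in parental and -0.33 in SLFN11-KO cells.

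The next comparison asked what the initiation map looked like when ATR was inhibited together with camptothecin. Compared with camptothecin alone, the libraries with VE-821 had 4.23% more MACS2 peaks in parental cells (log2 ratio 0.06, interval 0.05 to 0.07) and 8.74% more in SLFN11-KO cells (0.12, interval 0.11 to 0.13). The 1 Mb regions below were ranked by their ratio to the camptothecin list, so an extreme number in that list is part of how they were chosen, and part of the difference to the VE-821 list can follow from that choice. In SLFN11-KO cells chromosome X from 97 to 98 Mb had 22 peaks against 7, chromosome 18 from 41 to 42 Mb had 26 against 9, chromosome 5 from 20 to 21 Mb had 16 against 5, and chromosome 4 from 28 to 29 Mb had 18 against 6. In parental cells chromosome 9 from 16 to 17 Mb had 32 against 13, chromosome 1 from 79 to 80 Mb 20 against 7, and chromosome 11 from 38 to 39 Mb 20 against 8. Among the lowest ratios in parental cells were regions beside centromeres: chromosome X from 58 to 59 Mb had 21 with VE-821 and 45 without, and chromosome 7 from 61 to 62 Mb had 16 and 30. In SLFN11-KO cells the same X region had 25 with VE-821, 32 with camptothecin alone and 22 with DMSO. With SICER islands the relative log2 ratios in SLFN11-KO cells were 0.72 against 1.46 with MACS2 peaks for the X region from 97 to 98 Mb, 0.81 against 1.36 for that of chromosome 18 and 0.88 against 1.39 for that of chromosome 4. In parental cells they were 2.09 against 1.21 for chromosome 11 and -0.58 against -0.95 for chromosome 7. Of the peaks with VE-821, 71.3% in parental and 68.1% in SLFN11-KO cells overlapped a peak of camptothecin alone. In the SICER lists the parental direction was the opposite, with a change of -10.5% in islands with VE-821 (log2 ratio -0.16), and the SLFN11-KO log2 ratio was 0.01. Among MACS2 peaks with a score of at least 30 the log2 ratios were 0.59 in parental and 0.31 in SLFN11-KO cells, so the larger one moved from SLFN11-KO to parental cells.

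Regions were then followed over the 3 lists of a line. In parental cells 27721 of 52241 regions called with DMSO and not with camptothecin (53.1%, 52.6% to 53.5%) carried a peak in the library with VE-821, and in SLFN11-KO cells 31702 of 66209 (47.9%, 47.5% to 48.3%). A region missed by 1 list can be called in another by chance of detection alone, so the mirrored share was computed as well. Of regions called with DMSO and not with VE-821, 34.4% (33.9% to 34.9%) in parental and 29.7% (29.3% to 30.1%) in SLFN11-KO cells had a peak with camptothecin alone, the shallower library in parental cells. Of regions that had a peak with camptothecin and none with DMSO, 33.3% (32.9% to 33.7%) in parental and 31.9% (31.5% to 32.3%) in SLFN11-KO cells had one with VE-821. The corresponding SICER shares were 37.7% and 39.9% for regions missing with camptothecin, 37.1% and 31.4% for those missing with VE-821, so that the parental shares were nearly alike, and 22.1% and 27.6% for regions seen with camptothecin and not with DMSO.

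SLFN11-KO and parental cells were then compared within each treatment, which asked where the map depended on SLFN11. With DMSO the SLFN11-KO library had 3.83% more peaks than the parental one (log2 ratio 0.05, interval 0.05 to 0.06). With camptothecin it had fewer, with a log2 ratio of -0.10 (-0.11 to -0.10), and with camptothecin and VE-821 the log2 ratio was -0.04 (-0.05 to -0.03). Regions on chromosome X were among those with more peaks in SLFN11-KO cells: X from 29 to 30 Mb had 18 against 6 with DMSO, and with camptothecin and VE-821, X from 87 to 88 Mb had 19 against 8 and X from 146 to 147 Mb had 38 against 18. Chromosome 4 from 164 to 165 Mb had 25 against 11 and chromosome 18 from 38 to 39 Mb had 20 against 8 with DMSO. With camptothecin, chromosome 4 from 134 to 135 Mb had 26 in SLFN11-KO and 12 in parental cells, and chromosome 6 from 127 to 128 Mb had 17 and 37. Chromosome 4 from 117 to 118 Mb had 16 peaks in SLFN11-KO and 6 in parental cells with camptothecin, but its relative SICER log2 ratio was -0.06. The other regions kept their direction with SICER islands but lay nearer to the genome-wide ratio. With DMSO the relative log2 ratios were 0.63 against 1.45 with MACS2 peaks for X from 29 to 30 Mb, 0.49 against 1.09 for chromosome 4 and 0.27 against 1.22 for chromosome 18, where there were 8 islands against 7. With camptothecin they were 0.34 against 1.19 for chromosome 4 from 134 to 135 Mb and -0.548 against -0.995 for chromosome 6. With both drugs they were 0.39 against 1.24 for X from 87 to 88 Mb and 0.25 against 1.10 for X from 146 to 147 Mb. Sharing of SLFN11-KO peaks with parental peaks was 74.2% with DMSO, 71.9% with camptothecin and 74.7% with camptothecin and VE-821. SICER islands were fewer in SLFN11-KO cells with DMSO (log2 ratio -0.09), the reverse of the MACS2 peaks, and among peaks with a score of at least 30 the camptothecin ratio was 0.15.

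Few single regions stood apart from the genome-wide ratio by more than counting error. Of the 2788 regions of 1 Mb ranked for camptothecin against DMSO in parental cells, 25 had a counting interval above the genome-wide ratio and 23 had one below it, together 1.72% of the regions. In SLFN11-KO cells the share was 0.999%, and between the lines it was 0.283% with DMSO, 0.509% with camptothecin and 0.211% with camptothecin and VE-821. A 95% interval leaves out 5% by chance only if both counts of a region are independent. The lists shared most of their peaks, so a share under 5% does not show that no region differed.

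Over all 15 pairs of libraries, the overlap of lists was lowest in pairs with a library of camptothecin alone. By the base-pair Jaccard index (shared over total covered length), these 9 pairs ranged from 0.485 to 0.548, below the 6 pairs without one, which ranged from 0.563 to 0.602. Within each of these sets, MACS2 lists of 1 line had the highest median. Of the 6 pairs without such a library, the 2 of 1 line had a median of 0.601, the 2 of 1 treatment 0.580 and the 2 that shared neither 0.580. Of the 9 pairs with one, the 4 of 1 line had a median of 0.535 and the 4 that shared neither 0.520. The camptothecin libraries were also the least alike of all pairs, with 0.485 between parental and SLFN11-KO cells. Both were the shallowest libraries of known depth, which can lower the overlap of lists. Depth was thus not told apart from treatment here. Parental cells with DMSO and with camptothecin and VE-821 were the most alike, with 0.602. In the SICER lists the pairs with a camptothecin library ranged from 0.557 to 0.590 and the others from 0.610 to 0.625. There the 2 pairs of 1 line without a camptothecin library (0.621 and 0.625) did not stand apart from the other 4 (0.610 to 0.625).

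Camptothecin libraries held relatively fewer peaks in peak-poor parts of the genome, in both lines. The genome was divided into 1 Mb bins, ranked into quintiles by peak number in the DMSO library of the other line, which took no part in the comparison. In the quintile with the fewest peaks, parental cells had 8091 peaks with camptothecin and 9222 with DMSO, a change of -12.3%, and SLFN11-KO cells had 7749 and 10158, a change of -23.7%. In the densest quintile the change was 7.22% in parental and -0.206% in SLFN11-KO cells. The log2 ratio of the densest quintile minus that of the sparsest was 0.29 ± 0.02 in parental and 0.39 ± 0.02 in SLFN11-KO cells (SE from a jackknife over 23 chromosomes, which describes evenness along the genome and not replicate error). With SICER islands it was 0.67 ± 0.02 and 0.58 ± 0.02. The difference between the lines turned with the caller, at 0.10 with MACS2 and -0.08 with SICER.

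Compared with the same camptothecin libraries, the sparse quintile with VE-821 held more peaks, by 27.1% in parental cells (10283 against 8091) and by 41.2% in SLFN11-KO cells (10939 against 7749). In the SICER lists this was 20.3% in SLFN11-KO but 0.587% in parental cells (5144 islands against 5114), where the other quintiles changed by -8.59% to -12.9%. In the densest quintile of MACS2 peaks the change was -0.508% and 0.950%. The densest minus the sparsest quintile gave -0.35 ± 0.02 in parental and -0.48 ± 0.02 in SLFN11-KO cells, and with SICER islands -0.15 ± 0.03 and -0.27 ± 0.02. Between the lines the same quantity was -0.03 ± 0.02 for SLFN11-KO over parental cells with camptothecin and -0.16 ± 0.02 with camptothecin and VE-821. The former was 0.06 ± 0.02 with SICER islands, -0.21 ± 0.02 with lists of equal length and -0.25 ± 0.03 with a score of at least 30. The latter was -0.06 ± 0.02 with SICER islands and -0.02 ± 0.03 with a score of at least 30. For DMSO no such value was computed, because no DMSO library outside the comparison existed to rank the bins.

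Read counts were also compared in 31176 fixed regions that SICER called over most of their length in all 6 lists. No region was thus present in one list and absent from another, although parts of a region could still be uncalled in a list. Regions that a camptothecin list missed were left out, which can hide a loss in sparse bins. In parental cells the share of these reads in the sparsest quintile was lower with camptothecin than with DMSO, with a log2 ratio of -0.16 ± 0.04 over 735 regions, and the densest minus the sparsest quintile gave 0.17 ± 0.04. Part of this lay in the length called, for which the same value was 0.08 ± 0.02; for reads per covered bp it was 0.09 ± 0.03, and 0.04 ± 0.03 in the 4730 regions called over at least 80% of their length. In SLFN11-KO cells the value for reads was -0.03 ± 0.04, with 0.01 ± 0.04 in the sparsest quintile. The second and the third quintile there had 0.09 ± 0.02 and 0.07 ± 0.02 and the densest -0.012 ± 0.006, opposite to the direction of the peak numbers. With VE-821 over camptothecin alone it was -0.17 ± 0.03 in parental and 0.02 ± 0.04 in SLFN11-KO cells. Comparing SLFN11-KO with parental cells, it was -0.19 ± 0.03 with camptothecin and -0.01 ± 0.03 with camptothecin and VE-821.

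**Figure D2:**
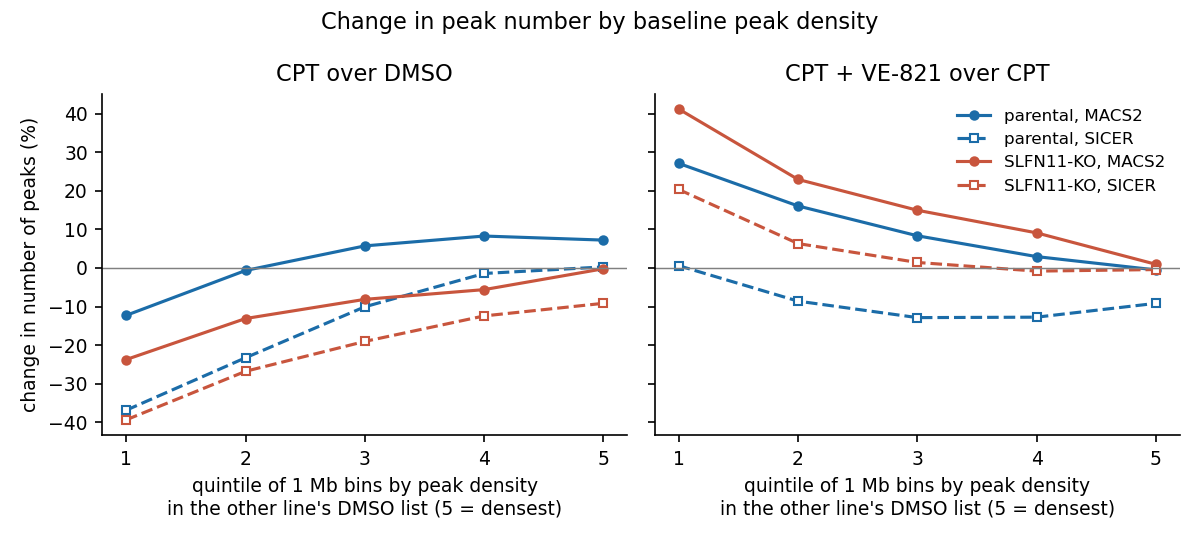
Percent change in the number of MACS2 peaks (filled circles) and SICER islands (open squares) in each quintile of 1 Mb bins, from the sparsest (1) to the densest (5), for camptothecin over DMSO (left) and camptothecin with VE-821 over camptothecin alone (right), with 1 library per treatment and line. MACS2 changes in quintile 1 were -12.3% in parental (blue) and -23.7% in SLFN11-KO cells (red) on the left, and 27.1% and 41.2% on the right.

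Along the chromosomes, the camptothecin libraries of both lines differed from DMSO in a similar pattern. Chromosomes can differ in peak density, so this pattern may partly restate the density result above. The lower depth of both camptothecin libraries was not told apart from it either. Relative to the genome-wide ratio, chromosome 17 had a higher log2 ratio of camptothecin over DMSO, with 0.09 in parental and 0.07 in SLFN11-KO cells, as did chromosome 19 with 0.06 and 0.08 and chromosome 22 with 0.05 and 0.11. The counting interval of chromosome 22 included 0 in parental cells. Chromosome X was lower, with -0.07 and -0.11, although its share of reads in the fixed regions had a log2 ratio of -0.10 ± 0.03 in parental and -0.01 ± 0.06 in SLFN11-KO cells. Also lower in peak number were chromosomes 5 (-0.05 and -0.06) and 18 (-0.06 and -0.08). Chromosome 20 had -0.06 in parental and 0.08 in SLFN11-KO cells, but 0.04 and 0.06 with SICER islands. In parental cells, SICER islands gave 0.14 for chromosome 22, -0.16 for X and -0.11 for chromosome 5. Across the 23 chromosomes, which are not independent replicates, Pearson's r between the lines was 0.726 and Spearman's rho 0.735. Without chromosomes 16 and 17, the farthest from the median, r was 0.702. With SICER islands r was 0.971.

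The ratio of VE-821 over camptothecin alone shares the camptothecin library of its line with the ratio above, so an opposite order of chromosomes within a line can come from that library alone. Chromosome X had relative log2 ratios of 0.08 in parental and 0.13 in SLFN11-KO cells, and chromosome 4 had 0.06 and 0.11. Chromosome 17 had -0.11 and -0.10, chromosome 19 had -0.10 and -0.13, and chromosome 22 had -0.09 and -0.14. Pearson's r between the lines was 0.884 and Spearman's rho 0.838. With SICER islands r was 0.492, and without chromosomes 20 and X it was 0.290. Between lines, where no library is shared, the r of camptothecin over DMSO in parental cells with VE-821 over camptothecin in SLFN11-KO cells was -0.746 with MACS2 and -0.842 with SICER lists. The reverse pairing gave -0.872 with MACS2 but -0.070 with SICER lists. In parental SICER lists chromosomes 4, 13, 18, 19 and 22 had the opposite sign, and so did others, such as chromosomes 2 and 8. Chromosome 17 had -0.02 there. In SLFN11-KO cells SICER islands gave 0.06 for X, 0.03 for chromosome 4, -0.05 for 17, -0.01 for 19 and -0.06 for 22.

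Relative to the genome-wide ratio, SLFN11-KO cells had more peaks on chromosome X than parental cells in every treatment, with log2 ratios of 0.12 with DMSO, 0.08 with camptothecin and 0.13 with camptothecin and VE-821. Over the 3 treatments as pairs the mean was 0.11 ± 0.03 (SD, n = 3), with an exact sign-flip permutation p of 0.25, two-sided, the smallest that 3 pairs can give. SICER islands gave 0.07, 0.09 and 0.10. Other chromosomes came close to X in some lists and were level with it in others. With camptothecin, chromosome 20 had 0.07 in MACS2 and 0.09 in SICER lists, where X also had 0.09. With DMSO, chromosomes 20 and 22 both had 0.07 in SICER lists, as X did. In 879 regions of X that were called in all SICER lists, the log2 ratio of read shares was 0.09 ± 0.03 with DMSO, 0.19 ± 0.02 with camptothecin and 0.10 ± 0.03 with camptothecin and VE-821 (SE from a jackknife over 16 segments of 10 Mb). The highest autosome reached 0.04, 0.06 and 0.06 in these read shares. For reads per covered bp the X values were 0.05 ± 0.03, 0.13 ± 0.02 and 0.03 ± 0.03.

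**Figure D3:**
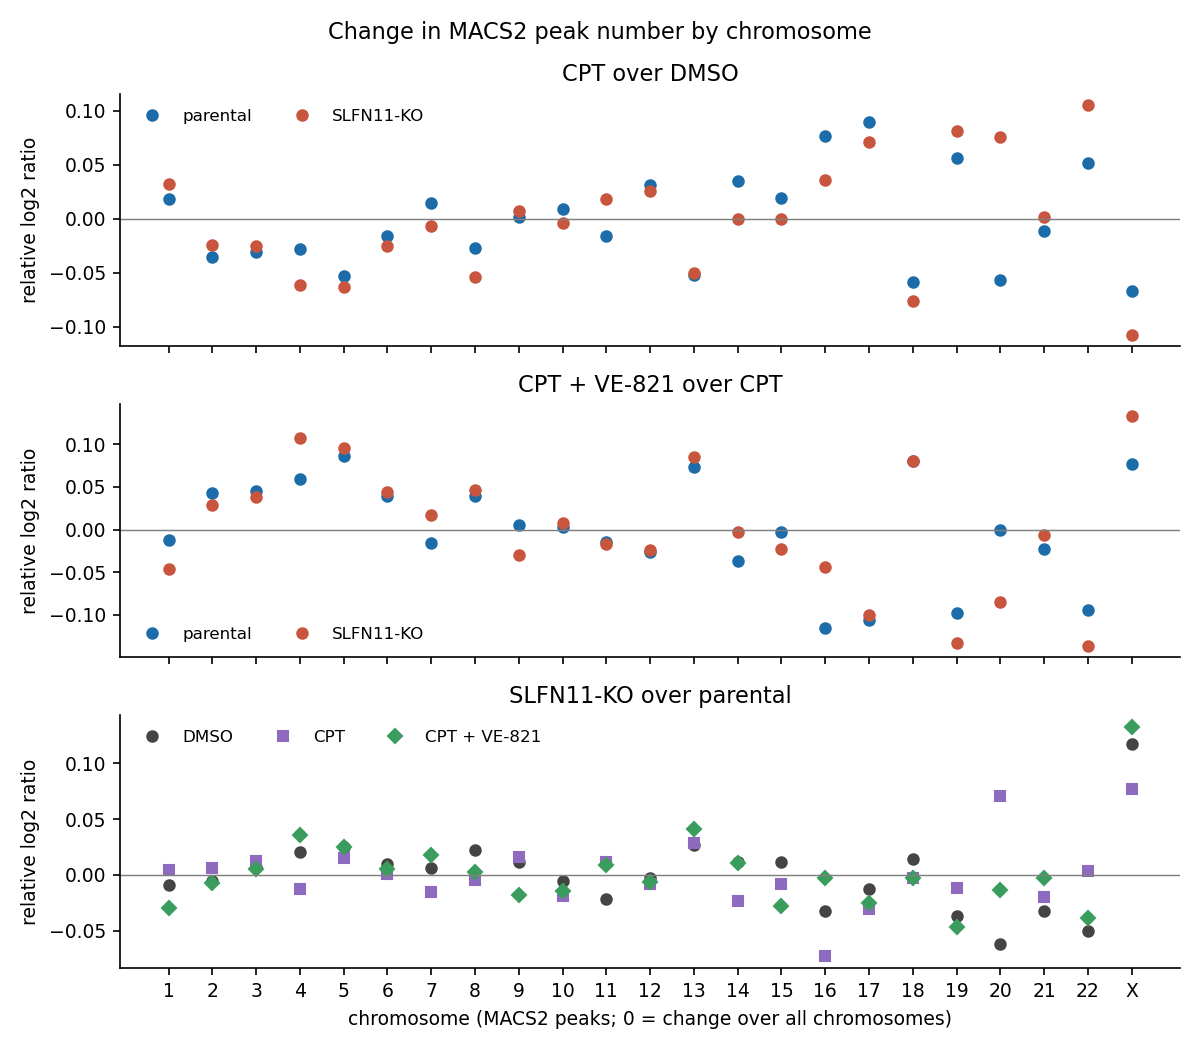
Log2 ratio of MACS2 peak numbers per chromosome minus the genome-wide log2 ratio, for camptothecin over DMSO (top), camptothecin with VE-821 over camptothecin (middle) and SLFN11-KO over parental cells in each treatment (bottom), where each point comes from 1 library per side. Chromosome X lay at 0.12, 0.08 and 0.13 in the bottom panel, with chromosome 20 next to it at 0.07 with camptothecin.

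Most parental peaks gained with camptothecin did not overlap one gained in SLFN11-KO cells. Overlap with peaks that SLFN11-KO cells had both with DMSO and with camptothecin was not counted. Parental camptothecin peaks absent from the DMSO list were weak, with a median score of 20.7 against 27.4 for shared ones. Detection alone can thus keep this overlap low. Of 65653 parental peaks present with camptothecin and not with DMSO, 8556 (95% Wilson interval 12.8% to 13.3%) overlapped a peak that SLFN11-KO cells also had with camptothecin only, against 2.36% after shifts by 20 to 100 kb. A similar share, 14.5%, overlapped a peak that SLFN11-KO cells had with DMSO only. This was a larger set (69442 peaks against 51316), and no shifted value was computed for it. Of 54702 parental peaks lost with camptothecin, 12569 (22.6% to 23.3%) overlapped a peak lost in SLFN11-KO cells, against 2.77% after shifts, and 10.5% overlapped one gained there. Of the peaks lost in both lines, 39.9% were present in both libraries with VE-821 and 19.7% in neither. Of those gained in both lines, 20.5% were present in both and 40.2% in neither. Peaks lost in both lines were by definition missing from the camptothecin libraries, the shallowest of known depth. Finding more of them in other lists can follow from detection alone, and no mirrored share was computed here.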

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

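The tests in this part were chosen after the result was seen. With camptothecin the number of MACS2 peaks was higher than with DMSO in parental cells (log2 ratio 0.08) and lower in SLFN11-KO cells (-0.08), a difference of -0.16 between lines that moved in opposite directions; the difference was not tested, since each group had 1 library. The opposite directions were tied to the peak caller: with SICER islands both lines moved down, by a log2 ratio of -0.093 in parental and -0.23 in SLFN11-KO cells. SLFN11-KO cells were lower with both callers (-0.16 and -0.14), but not among MACS2 peaks with a score of at least 30, where the log2 ratios were -0.38 in parental and -0.33 in SLFN11-KO cells and the difference turned to 0.047. Depth was no clear guide. The tag number dropped with camptothecin by almost the same log2 ratio in both lines (-0.49 in parental and -0.47 in SLFN11-KO cells, a difference of 0.012). Yet the SLFN11-KO camptothecin library was the shallowest in absolute terms of those with a known depth. A different response of initiation without SLFN11 was not tested, and with 1 library per group it cannot be told apart here from an effect of depth.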

How the results depend on the processing

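The alternatives with a score of at least 30, with reads or reads per covered bp in fixed regions, with regions called over at least 80% of their length, with equal list lengths for the density result and with shifts by 20 to 100 kb were chosen after seeing the data; the others were planned. No fit with a replicate block was possible because replicate numbers were given in accession order only, with 1 library per group; pairing the lines over the 3 treatments was possible, with a smallest exact p of 0.25. The planned minimum score of 10 removed no peak and so says nothing about stability. Alternatives on gene position, gene lists and gene flanks were not run. The depth of 1 library is unknown, and depth can affect which weak peaks are called. A score of 30 was reached by 30.7% of the peaks of the parental camptothecin library, against 42.1% with DMSO. These shares did not follow depth throughout. The share was 36.5% in the shallower SLFN11-KO camptothecin library. In parental cells with both drugs it was 44.4%, although that library was shallower than the one with DMSO. Scores may not be comparable between separately called lists, so a change of direction at this score can reflect the score scale. The cause was not tested for any change below, except as given under the other headings. Comparisons are listed in this order: camptothecin over DMSO in parental and in SLFN11-KO cells, camptothecin with VE-821 over camptothecin in parental and in SLFN11-KO cells, and SLFN11-KO over parental cells with DMSO, with camptothecin and with both drugs.

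SICER gave 150162 islands in parental cells with both drugs, and 143508 and 144884 in SLFN11-KO cells with camptothecin and with both drugs. With a score of at least 30 the lists had 93010, 71645 and 108149 peaks in parental cells (DMSO, camptothecin, both drugs) and 99579, 79261 and 98149 in SLFN11-KO cells. Log2 ratios of SICER island numbers were -0.093, -0.23, -0.16, 0.014, -0.087, -0.23 and -0.052, so 3 turned: camptothecin and then VE-821 in parental cells, and the lines with DMSO. With a score of at least 30 they were -0.38, -0.33, 0.59, 0.31, 0.10, 0.15 and -0.14, so camptothecin over DMSO in parental cells and the lines with camptothecin turned. With peaks within 1 kb merged no direction changed, and the ratios that moved were 0.066 for camptothecin and 0.069 for VE-821 in parental cells, and -0.096 between the lines with camptothecin. SLFN11-KO minus parental cells gave, for camptothecin over DMSO, -0.14 with SICER islands, 0.047 with a score of at least 30 and -0.14 with peaks merged, and for VE-821 over camptothecin 0.17, -0.29 and 0.049, so both turned with that score. Shares of shared peaks were 81.9%, 84.8%, 82.5%, 79.2%, 84.9%, 83.2% and 83.3% with SICER islands, 78.8%, 79.6%, 54.5%, 61.3%, 72.4%, 62.9% and 75.5% with a score of at least 30, 71.3%, 72.7%, 69.6%, 68.8%, 75.0%, 67.2% and 72.1% with equal list lengths, and 44.6%, 46.2%, 44.2%, 41.8%, 51.4%, 40.1% and 48.2% when 50% of both peaks had to overlap. Median Jaccard indices with SICER islands were 0.589 for pairs of 1 line and 0.581 for pairs that shared neither line nor treatment.

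For the densest minus the sparsest quintile, with no value for DMSO between the lines, SICER islands gave 0.67, 0.58, -0.15, -0.27, 0.057 and -0.059. A score of at least 30 gave 0.54, 0.53, -0.71, -0.51, -0.25 and -0.018, and bins of 5 Mb gave 0.19, 0.28, -0.27, -0.37, -0.014 and -0.11. Equal list lengths gave 0.35, 0.25, -0.34, -0.29, -0.21 and -0.17. Reads in fixed regions gave 0.17, -0.026, -0.17, 0.020, -0.19 and -0.0064, so both values within SLFN11-KO cells changed sign, each within its error of 0. Reads per covered bp in these regions gave 0.089, -0.024, -0.11, 0.044, -0.11 and 0.032, and reads in regions called over at least 80% of their length gave 0.12, -0.15, -0.11, 0.14, -0.22 and 0.0051. Both turned the values within SLFN11-KO cells and the last, but none of these turned values lay clearly away from 0. Their errors were 0.045, 0.042 and 0.029 for reads per covered bp. In regions called over at least 80% of their length they were 0.14, 0.12 and 0.11. The correlation of the lines over chromosomes was 0.971 for camptothecin and 0.492 for VE-821 with SICER islands, and 0.930 for camptothecin with a score of at least 30. On X, SLFN11-KO over parental cells was 0.18 with DMSO and 0.30 with camptothecin at a score of at least 30, and kept its direction in all 3 treatments with SICER islands and with that score. For VE-821 over camptothecin in parental cells, only some chromosomes were checked. Among these, SICER islands turned the sign on chromosomes 19 (0.033), 22 (0.015), 4 (-0.030), 13 (-0.0025) and 18 (-0.00057). They turned it on others too, such as chromosomes 2 (-0.0010) and 8 (-0.012). They also turned it on chromosome 4 from 117 to 118 Mb for SLFN11-KO over parental cells with camptothecin (-0.063), the only sign change with SICER islands among the 29 regions of 1 Mb tested so. In 2 others the SICER value lay outside the counting interval of the MACS2 value: chromosome 2 from 179 to 180 Mb for camptothecin over DMSO in SLFN11-KO cells (0.071) and X from 146 to 147 Mb for the lines with both drugs (0.25). These intervals are wide, and many of the remaining 26 values changed by more than 1.5 times; the regions were picked as extremes of the MACS2 lists, so smaller values in another list are expected.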

Other observations

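The tests in this part were chosen after the results were seen. Some regions changed with camptothecin in both lines and with both callers. There were 4666 peaks that both DMSO libraries had and both camptothecin libraries lacked, in MACS2 and in SICER lists, against 1725 of the opposite kind. Of the 5 widest of the former, 3 had islands in both libraries with VE-821. At chromosome 1 from 5815119 to 5818088, SICER islands held 345 reads in parental and 190 in SLFN11-KO cells with DMSO, and 254 and 210 with VE-821. At chromosome 2 from 3298106 to 3300564 the reads were 370 and 208, and 305 and 124, and at chromosome 7 from 149244792 to 149247022 they were 219 and 96, and 100 and 111. The other 2 had an island with VE-821 in parental cells only. At the widest, chromosome 19 from 24062005 to 24065161, the reads were 321 and 310 with DMSO, and 208 with VE-821 in parental cells. At X from 144583126 to 144585805 they were 205 and 91, and 169, although a MACS2 peak was called there in SLFN11-KO cells with VE-821. Of the 5 widest of the latter, all 5 had a MACS2 peak or a SICER island in at least 1 of the libraries with VE-821. At chromosome 2 from 128673392 to 128676112, islands of 213 reads in parental and 139 in SLFN11-KO cells were seen with camptothecin, and with VE-821 only a MACS2 peak in parental cells. At chromosome 11 from 50577119 to 50579554 the islands held 381 and 337 reads with camptothecin, and 98 with VE-821 in parental cells. In 2 others the island reads were higher with VE-821 in 1 line. Chromosome 1 from 203304928 to 203307416 had 140 with camptothecin and 248 with VE-821 in parental cells. In SLFN11-KO cells it had 68 and no called island. Chromosome 2 from 25272284 to 25274805 had 76 and 114 in SLFN11-KO cells, but 308 and no called island in parental cells. The remaining one, chromosome 1 from 95530936 to 95533640, had 146 and 69 reads with camptothecin and only a parental MACS2 peak with VE-821. Reads are not scaled for depth, and both camptothecin libraries were shallow. The depth of the SLFN11-KO library with VE-821 is unknown, and a region without a called island can still hold reads.

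Of the ranked regions, 3 beside centromeres held more peaks with camptothecin than with either other treatment in both lines, a set put together after their values were seen: the X region from 58 to 59 Mb given above and those below. Chromosome 11 from 50 to 51 Mb had 22 peaks with DMSO, 33 with camptothecin and 21 with both drugs in parental cells, and 18, 33 and 21 in SLFN11-KO cells. Chromosome 7 from 61 to 62 Mb had 19, 30 and 16 in parental and 17, 21 and 15 in SLFN11-KO cells. Not every region beside a centromere did so in both lines, since chromosome 5 from 45 to 46 Mb had 10, 10 and 12 in parental and 10, 15 and 10 in SLFN11-KO cells. In the SICER lists chromosome 11 from 50 to 51 Mb had 25, 30 and 14 islands in parental and 15, 18 and 11 in SLFN11-KO cells, and chromosome 7 from 61 to 62 Mb had 15, 22 and 13, and 15, 16 and 13. X from 58 to 59 Mb had 18, 34 and 9 islands in parental cells but 17, 17 and 11 in SLFN11-KO cells, where camptothecin was no higher than DMSO. No filter for repeated sequence was applied here. The tags of both camptothecin libraries were also longer (70 bp against 63 to 66 bp in the others with a header). This cannot be told apart from treatment.

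Peak-poor regions had fewer MACS2 peaks with camptothecin in both lines, and more with VE-821 than in the same camptothecin libraries, except that parental SICER islands barely moved with VE-821 (0.587% in the sparsest quintile). Lower depth remains a candidate explanation in parental cells: in the fixed regions, reads per covered bp kept a log2 ratio of 0.089 ± 0.027 for the densest minus the sparsest quintile, but only 0.042 ± 0.026 in regions called over at least 80% of their length. In SLFN11-KO cells the former was -0.024 ± 0.045, and the second and the third quintile lay against the direction of the peak numbers (0.073 ± 0.022 and 0.051 ± 0.015), as did the second (0.14 ± 0.06) but not clearly the third (0.019 ± 0.025) in regions called over at least 80% of their length, where the densest minus the sparsest gave -0.15 ± 0.14, so the cause of the lower peak numbers stays open. The fixed regions had to be called in the camptothecin lists too, so regions lost there were left out. These read values therefore cannot decide on depth in either line. Library preparation cannot be told apart from treatment: the tags of both camptothecin libraries were 70 bp long, and those of the other libraries with a header 63 to 66 bp. An effect of camptothecin and of ATR inhibition on initiation stays open and was not tested.

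With camptothecin, the higher signal of chromosome X in SLFN11-KO cells was not a product of peak calling alone, since reads per covered bp, which calling more weak sequence would lower, had a log2 ratio of 0.13 ± 0.02, and 0.16 ± 0.05 in regions called over at least 80% of their length. With DMSO and with both drugs the ratios were 0.054 ± 0.029 and 0.034 ± 0.030, so an effect of peak calling cannot be told apart there. More copies of X in the knockout cells are a candidate explanation that these values cannot decide. Of 48 values, from the same 16 segments of 10 Mb in each of 3 treatments, 45 lay above 0. A difference in initiation along all of X could give the same. Extra copies alone would shift every treatment alike. The log2 ratio of read shares on X was 0.09 ± 0.03 with DMSO, 0.19 ± 0.02 with camptothecin and 0.10 ± 0.03 with both drugs. MACS2 peak numbers on X were not highest with camptothecin, at 0.12 with DMSO, 0.08 with camptothecin and 0.13 with both drugs. SICER islands gave a mean of 0.088 ± 0.013 (SD over the 3 treatments). Whether the treatments differed thus depended on the measure. The sheared genomic DNA, which could decide the number of copies, was not analysed here. Copy number and a difference in initiation therefore cannot be told apart.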
